A study of Gasterosteus aculeatus with 18 samples.

How the data were processed

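RNA was sequenced from 18 pools of threespine stickleback (Gasterosteus aculeatus) eggs, each a pool of 10 eggs from a clutch, sampled 72 hours after fertilization. The sample titles put 6 pools in each of 3 groups, control, low and high, and the series' design text gives 3 doses of cortisol, the main glucocorticoid of fish, of 0, 5 and 10 µg/L. The labels do not say whether pools with the same replicate number came from 1 clutch.

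The authors deposited 1 table of normalized values for 17253 genes in all 18 samples, with genes named by Ensembl identifier only. Its values are treated here as scores, that is, normalized counts that the authors had scaled and rounded to whole numbers before they were deposited; the file names them as normalized counts and its header holds only the sample names. FastQC, TopHat2 2.0.8, Bowtie2 2.1.0, TopHat, Cufflinks 2.2.0, Cuffdiff, HTSeq and edgeR are listed in the submitters' processing notes, without the step each was used for. The genome build and annotation release are not given in the sources used here. Every gene in the table exceeds a value of 5 in at least 2 samples, so genes of low expression had been removed.

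The scaling left a trace. Counts multiplied by a factor and rounded skip whole numbers at regular intervals when the factor is above 1 and pile up on some when it is below 1. A scan of the values under 300 gave a clear factor in 16 of the 18 columns (log-likelihood at least 40 above any factor more than 0.01 away), and factors near 1 in the other 2. On 7 simulated columns the largest error of the factor was 0.0048. Dividing each column's total by its factor gave an estimated depth of 9.65 to 12.4 M counted reads per library, while the deposited totals ran from 8.36 to 15.2 M. In each column at least 99.19% of the values under 300 can be reached as a rounded count times the factor. The rounded values are not exact multiples of a step, however, and the reads themselves were not recovered. No count model was fitted here. The test was made on a log scale, as fixed for normalized values before the data were examined.

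Genes entered the tests when their mean over the 18 samples was at least 11.4, a fixed share of the mean column total, which kept 16103 genes and left out 1150. Values were transformed to log2(value + 1), and fold changes are on that scale, which understates the change of genes with low values. All 18 samples were fitted together in limma 3.58.1 (R 4.3.3) with a variance trend, and the contrasts low against control, high against control and high against low, an F test over the 3 groups and a linear trend over the doses were tested with Benjamini-Hochberg adjustment at 0.05. Errors of fold changes are standard errors from limma. Comparisons of 1 value per library used two-sided exact sign-flip tests over the 6 pairs with the same replicate number, whose smallest possible p is 0.03125. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used for the factor scan and the plots.

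The groups share the replicate numbers 1 to 6, but the labels do not say that a number marks 1 clutch. The fit without a replicate block was therefore fixed as the main one and the fit with the block as the alternative. Whether the numbers pair the samples was decided from the correlations of the libraries and not from the calls of either fit. After removal of the group means, same-numbered libraries of different groups correlated across genes with a mean r of 0.78 (lowest 0.67, highest 0.90), and in 18 of 18 comparisons a library correlated best with the library of its own number. Every pair exceeded the threshold of 0.1 set beforehand, a low bar, as libraries of different numbers and groups correlated at up to r = 0.76. By that criterion the numbers were taken to pair the samples. That pairing comes from the data, not from the labels, and blocked values are given beside the main ones. No 2 libraries held the same values (at most 2.99% of genes were equal).

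The procedure was tested on simulated data for the comparison of high with control, with the real means, replicate-number differences and residual spread of the 16103 genes and 200 genes changed. Without the block it recovered 0% of changes of 0.5 and 35.0% of changes of 1 on the log2 scale. With the block it recovered 45.5% and 90.5%, with 7 and 8 false calls. The residual spread was drawn for each gene on its own, whereas genes of real libraries vary together. These false calls therefore do not show how many to expect in the real data. Of the unchanged genes, 0.113% (with changes of 0.5) had an unadjusted p under 0.05 without the block and 5.26% with it.

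The file does not pair its identifiers with gene names, and 0 of the 17253 identifiers are in the reference gene table used here. The 38 gene lists fixed before the data were examined, among them the ABC transporters, and the rule that names genes by symbol therefore could not be applied and are not analysed here. The identifiers printed follow the rest of that rule, the 2 higher and the 2 lower genes with the smallest p in the main fit of each comparison. The exception is ENSGACG00000013729 of the dose trend, singled out after its values were seen. Alternatives were the replicate block, pseudocounts of 0.1 and 5, no filter, a filter 5 times as strict, quantile normalization, median-ratio rescaling, other variance models, sample weights, an adjusted p under 0.10, fits of 2 groups only and fits without each library. Combinations of the block with those settings were added after the data were seen. So were blocked fits with each of 9 covariates or pairs of covariates: the estimated reads, the column total, the number of genes at a value of 5 or less, the score on each of 5 principal axes of the control pools, and axes 1 and 2 together.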

Results

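The experiment compared messenger RNA of stickleback egg pools at 3 levels of cortisol, which stood for a baseline, a level brought on in mothers by predators and a level above the physiological range. Each group held 6 egg pools. The estimated depth was 10.49 ± 0.530 M reads (SD, n = 6) in control, 11.59 ± 0.873 M in low and 10.99 ± 0.686 M in high libraries. Low libraries were the deeper ones in 6 of 6 pairs with control (exact sign-flip test, p = 0.03125, adjusted over 12 such tests 0.0938). The number of genes with a value of 5 or less was 532 ± 109 in control, 458 ± 94.0 in low and 652 ± 310 in high libraries, with the high library of replicate number 3 at 1220. Nothing in the labels states that the pools came from separate clutches, so the p-values measure only the spread seen in these pools. Without the block that is the spread between the pools of a group. In the blocked fit and the sign-flip tests it is the spread of differences within replicate numbers.

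Differences between replicate numbers dominated the expression profiles. The replicate number accounted for 79.7% of the variance of the log2 values over the 16103 genes, the dose group for 6.43% and the remainder was 13.9%. Pools numbered 1 and 6 lay on one side of the first principal component, which held 48.0% of the variance, and pools 3, 4 and 5 on the other. Within each number the high library had the highest score on the second component, which held 19.8%. The median residual SD per gene was 0.45 on the log2 scale without a replicate block and 0.20 with it.

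**Figure D1:**
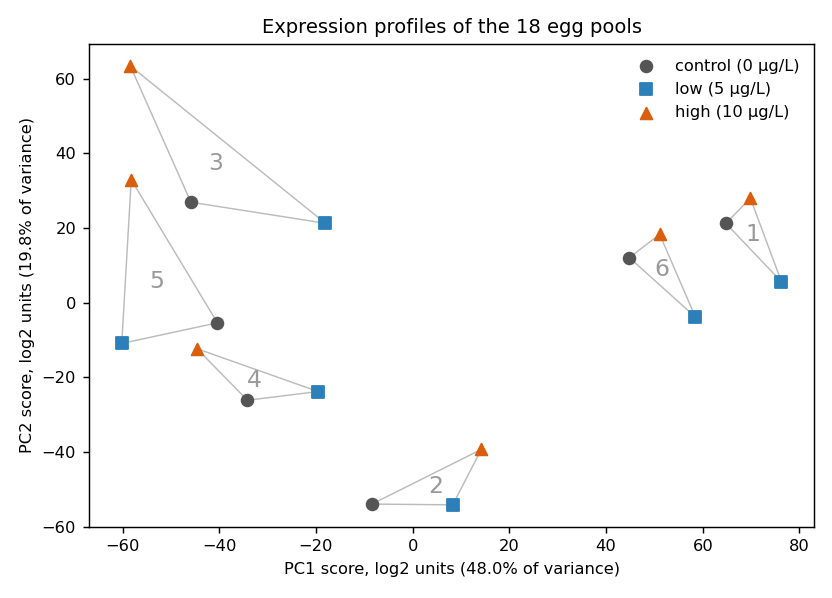
Scores of the 18 egg pools on the first 2 principal components of log2 normalised read counts, in log2 units, with 48.0% (x axis) and 19.8% (y axis) of the variance. Colour and marker give the dose group, and grey lines join the 3 pools with the same replicate number (grey digit); the high pool is the uppermost of each triplet, and high pool 5 lies nearer to control pool 3 than to the other pools of number 5.

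Low cortisol against control asked whether the dose that stands for a mother's encounter with predators changed embryonic expression. No gene was called higher or lower. Among the genes with the smallest p, ENSGACG00000018327 had a normalised read count of 38.0 ± 10.4 (SD, n = 6) in low pools and 22.3 ± 5.85 in control pools, and it was higher in the low pool of 6 of 6 pairs. ENSGACG00000013120 had 16.0 ± 6.96 in low pools against 7.50 ± 3.94 in control pools, again in the same direction in 6 of 6 pairs. ENSGACG00000020231 had 443 ± 136 in low pools against 664 ± 96.3 in control pools, and ENSGACG00000020054 had 168 ± 22.8 against 231 ± 31.2, both lower in 6 of 6 pairs. In high pools the counts of these genes were 29.7 ± 3.4, 12.5 ± 3.8, 689 ± 175 and 189 ± 33.2 in the order named. ENSGACG00000020231 was thus back at its control level, while the others lay between their control and low means. Agreement of the pairs in the differences between low and control pools is favoured by the choice of genes with the smallest p. None of these differences passed the test in limma without the block (log2 fold changes of 0.74 ± 0.23, 1.04 ± 0.37, -0.63 ± 0.21 and -0.46 ± 0.14 in the order named, SE, adjusted p = 1 for each). With the replicate block the adjusted p from limma was 0.147, 0.251, 0.0573 and 0.117 in the same order.

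Over all genes, limma called 0 of 16103 in low against control both without and with the block. At an unadjusted p under 0.05 there were 78 genes without the block and 1782 with it. Chance gives 805 where unchanged genes reach that p at its nominal rate. Without the block they did not, as 0.113% of them reached it in the simulation of high against control. The 78 genes therefore cannot be read against 805. The blocked count of 0 rose to 263 without control pool 5, to 169 without low pool 5 and to 5 without control pool 4, and 372 genes were called without replicate number 5, of which 292 were lower in low pools. With the block it was 1067 (317 higher, 750 lower) with sample weights and 15, all lower, at an adjusted p under 0.10.

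High cortisol against control compared the dose above the physiological range with untreated pools. With the replicate block, 117 genes were higher and 71 were lower in high pools. The called changes were moderate, with a median 1.43-fold increase among the higher genes and a median 1.49-fold decrease among the lower ones, and 12 higher and 11 lower genes changed by more than 1 on the log2 scale. Of the 117 higher genes 108 were higher in 6 of 6 pairs, and of the 71 lower genes 64 were lower in 6 of 6 pairs, an evenness that the blocked test favours in the genes it calls.

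The gene with the smallest p without the block, ENSGACG00000018842, had 516 ± 57.2 (SD, n = 6) in high pools against 1071 ± 341 in control pools and 899 ± 297 in low pools, a log2 fold change of -1.002 ± 0.22 (SE) from control to high. ENSGACG00000016134 was lower in 5 of 6 pairs, at 35.0 ± 11.6 against 56.3 ± 16.3 in control pools. ENSGACG00000015348 rose to 546 ± 73.4 from 340 ± 74.9 in control pools and 351 ± 78.6 in low pools, and ENSGACG00000010215 to 74.8 ± 13.4 from 48.3 ± 11.7 in control pools and 47.5 ± 13.9 in low pools. In the blocked fit limma gave adjusted p-values of 0.00284, 0.0423, 0.00121 and 0.0397 in the order named. Without the block limma called 0 of 16103 genes, with 158 at an unadjusted p under 0.05, and the adjusted p of each of these 4 genes was 1. The blocked count of 188 fell to 54, 24, 68, 77 and 119 without control pools 2, 3, 4, 5 and 6 in turn, and to 86, 64, 23 and 54 without high pools 1, 3, 5 and 6. It was 602 (289 higher, 313 lower) with sample weights, 506 (286 higher, 220 lower) at an adjusted p under 0.10, 19 without the variance trend, 1 with the estimated depth or the score on the second axis of the control pools as a covariate, 440 with the column total and 59 with the number of genes at a value of 5 or less.

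**Figure D2:**
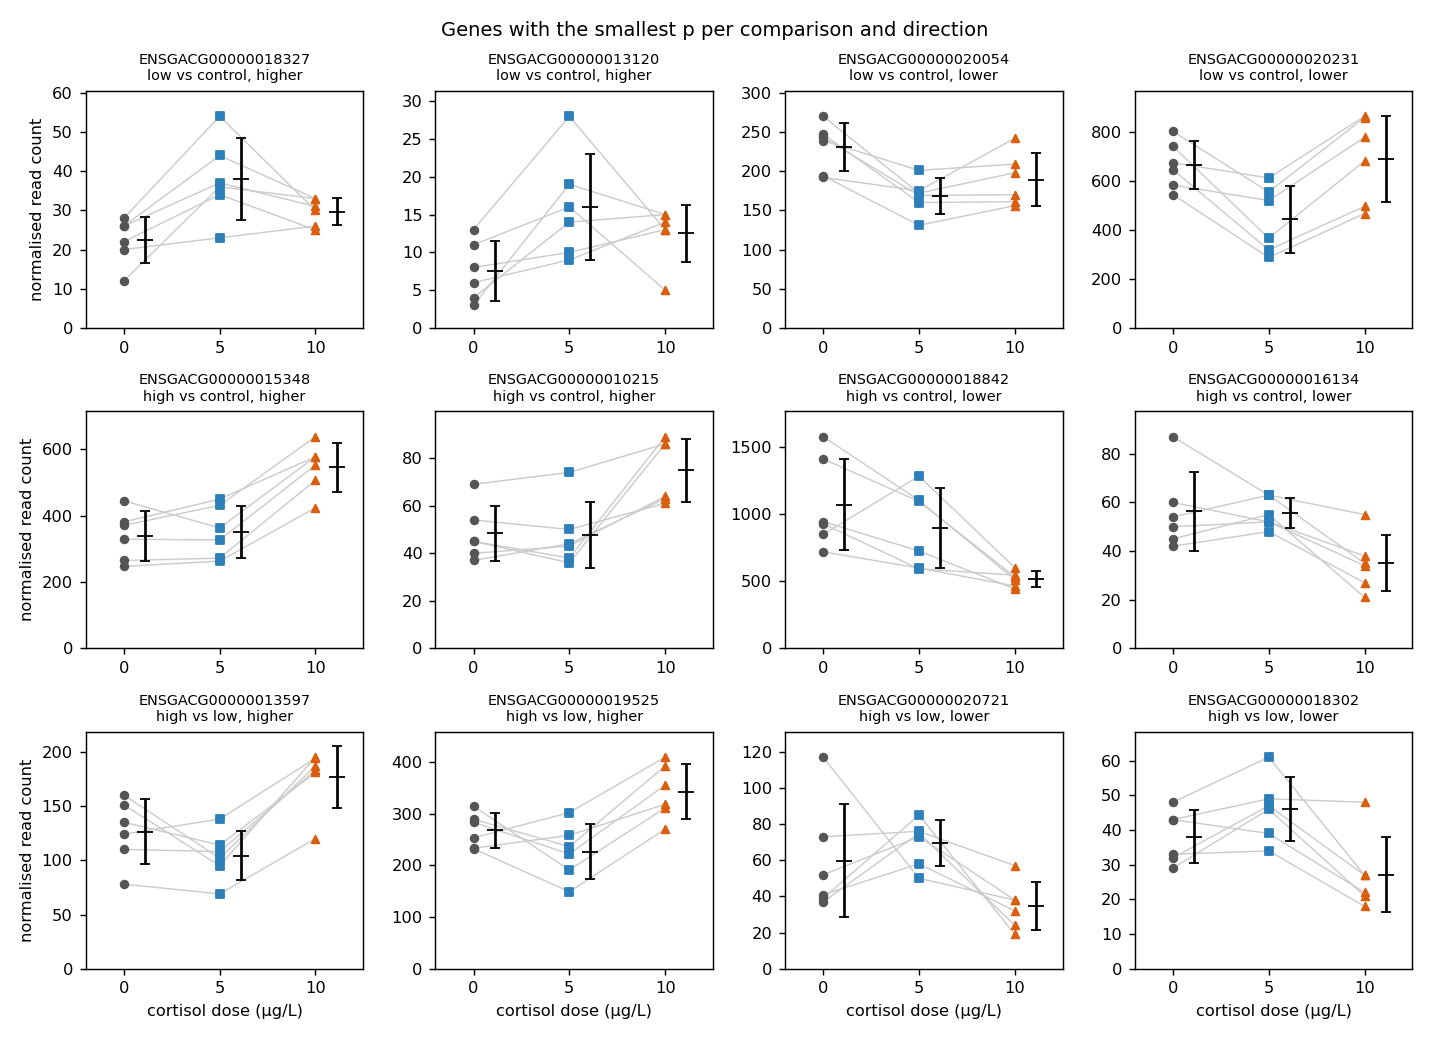
Normalised read count (y axis) against cortisol dose in µg/L (x axis) for the 12 genes with the smallest p, 2 higher and 2 lower in each of the 3 comparisons. Points are single pools, grey lines join pools with the same replicate number, and black bars give the mean ± SD of 6 pools; ENSGACG00000018842 falls from 1071 in control to 516 in high pools.

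High against low cortisol compared the 2 treated groups. With the replicate block, 700 genes were higher and 600 lower in high pools. The median change was 1.35-fold among the higher and 1.59-fold among the lower genes, and 44 higher and 101 lower genes changed by more than 1 on the log2 scale. The direction was the same in 6 of 6 pairs for 565 of the 700 and 463 of the 600 genes, which the blocked test again favours.

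The 2 sets of genes differed in abundance. The higher genes had a median normalised read count of 375 over all pools and the lower genes one of 137. Among called genes with a mean log2 value over 9, 261 were higher and 106 lower, while among those under 5 it was 26 higher and 93 lower. Over all genes in these classes, called or not, the median log2 difference between high and low pools was 0.047 in the class over 9, above 0 in 6 of 6 pairs, and -0.14 in the class under 5, below 0 in 6 of 6 pairs. The 100 most abundant genes of each library took 31.5% of its total in high and 29.8% in low pools, a larger share in high pools in 6 of 6 pairs (mean difference 1.73 ± 1.98 percentage points, SD, exact sign-flip test, p = 0.03125, adjusted 0.0938). Genes with a value of 5 or less were also more numerous in high than in low pools in 6 of 6 pairs.

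ENSGACG00000013597 had 177 ± 28.3 (SD, n = 6) in high pools, 104 ± 22.7 in low pools and 126 ± 29.8 in control pools. ENSGACG00000019525 had 343 ± 52.7 in high pools, 226 ± 53.1 in low and 267 ± 33.2 in control pools. ENSGACG00000020721 was lower in high pools, at 34.7 ± 13.3 against 69.5 ± 12.9 in low and 59.8 ± 31.03 in control pools, and ENSGACG00000018302 likewise, at 27.2 ± 10.8 against 46.0 ± 9.25 and 38.0 ± 7.64. In each of the 4 genes the control mean lay between the low and the high mean. The direction between low and high held in 6 of 6 pairs, which the choice of these genes by smallest p favours. In limma with the block their adjusted p-values were 0.000548, 0.00215, 0.0104 and 0.00722 in the order named, and without it 0.9999 for each. Without the block 0 of 16103 genes were called, with 385 at an unadjusted p under 0.05. The blocked count of 1300 was 656, 692 and 633 without low pools 1, 3 and 6, and 645 and 655 without high pools 3 and 5. It was 2491 with sample weights, 2150 at an adjusted p under 0.10 and 857 without the variance trend, and, with 1 covariate each, 36 with the number of genes at a value of 5 or less, 400 with the estimated depth, 707 with the column total, and 0 and 55 with the scores on the second and the third axis of the control pools.

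The control pools lay between the treated groups for most genes that differed between high and low. Control was intermediate for 620 of the 700 higher genes and 560 of the 600 lower genes. The median of the higher genes was 0.25 above control in high pools and on the other side of control in low pools, at -0.20 on the log2 scale. For the lower genes the medians were -0.39 in high and 0.27 in low pools. Because these genes were chosen for their difference between high and low, an intermediate control is in part set by that choice.

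Across all 16103 genes, which are not independent replicates, the low and the high effect relative to control correlated with r = 0.065. The same 6 control pools enter both effects. In 100 simulated data sets with unchanged groups, random combinations of the residuals of the blocked fit took the place of the effects. Their correlation averaged 0.49 (range 0.077 to 0.74), and 100 of 100 were at least as high as the observed value. The simulated effects spread less than the observed ones, with mean variances of 0.0249 for high and 0.0252 for low against control. A larger spread lowers a correlation at the same covariance, so the 100 of 100 does not by itself show that the effects disagree. The observed covariance was 0.00282 and the simulated mean 0.0124, a difference of -0.00956, and the observed value lay within the simulated range of 0.00184 to 0.0271, with 98 of 100 data sets at least as high. With the low effect taken from 3 replicate numbers and the high effect from the other 3, the correlation averaged -0.11 over 10 divisions (range -0.34 to 0.071). The spread of the gene effects, as a variance, was 0.0823 for high against low, 0.0518 for high against control and 0.0362 for low against control. Simulated unchanged groups reached as much in 0, 0 and 4 of 100 data sets.

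The linear trend over 0, 5 and 10 µg/L asked which genes moved in step with dose. With the block limma called 3 genes rising and 1 falling (adjusted p = 0.0493 for each). ENSGACG00000018842 was the falling gene, and ENSGACG00000015348 and ENSGACG00000013729 were among the rising ones, the last singled out after its values were seen. ENSGACG00000013729 had 98.7 ± 71.0 (SD, n = 6) in control, 120 ± 81.7 in low and 151 ± 64.8 in high pools, and the remaining rising gene had 50.2 ± 52.9, 56.8 ± 60.8 and 110 ± 98.7. In each of the 4 genes the difference between the low and high means was larger than that between the control and low means. Without the block limma called 0 of 16103, with 166 at an unadjusted p under 0.05. The trend count of 4 was 0 under a stricter filter, no filter, quantile normalization, a robust fit and no variance trend, 67 with sample weights and 34 at an adjusted p under 0.10, all with the block. The F test for any difference between the 3 groups called 853 genes with the block and 0 without it, where 151 had an unadjusted p under 0.05. The blocked F test count was 1301 without control pool 5, 377, 477 and 368 without low pools 1, 3 and 6, and 443 and 368 without high pools 3 and 5. It was 2594 with sample weights, 1643 at an adjusted p under 0.10 and 391 without the variance trend, and the trend count was 0 to 11 without single libraries.

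The profile of the high pools was displaced from that of the low pools along axes on which the control pools also differed from one another. On the second principal axis of the 6 control pools, one of 5 axes tested after the data were seen, which held 21.9% of their variance, the control SD was 32.7. High minus low was -19.5 ± 11.3 (SD of 6 pair differences) and high minus control -13.4 ± 9.15, below 0 in 6 of 6 pairs each (exact sign-flip test, p = 0.03125 each, 0.156 after adjustment over 15 tests on 5 axes). Low pools differed from control pools by 6.03 ± 12.4, in 5 of 6 pairs upward (exact sign-flip test, p = 0.25, adjusted 0.536). On the third axis, which held 16.3% of the control variance, high minus low was 11.98 ± 7.94, above 0 in 6 of 6 pairs (exact sign-flip test, p = 0.03125, adjusted 0.156). Across genes, which are not independent replicates, the high minus low differences correlated at r = -0.53 with the loadings of the second axis and at 0.32 with those of the third.

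**Figure D3:**
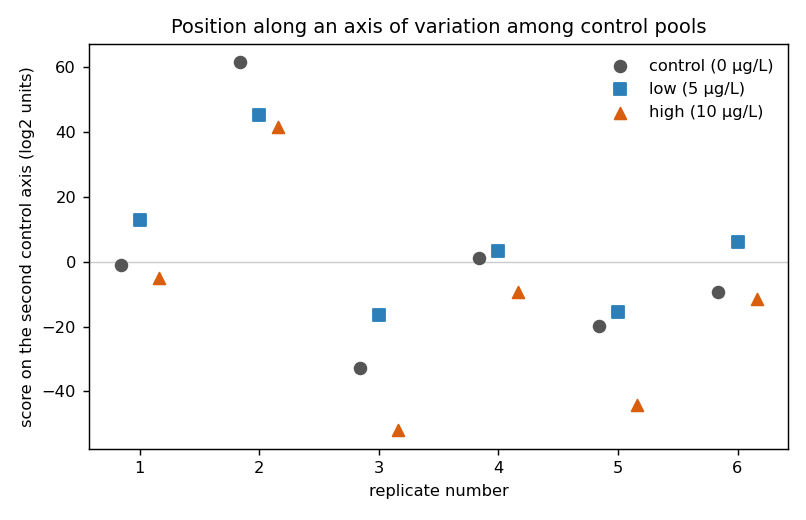
Score of each pool on the second principal axis of the control pools, in log2 units (y axis), by replicate number (x axis), with colour and marker for the dose group. The high pool has the lowest score in each of the 6 triplets, and the spread between numbers is wider than that between groups.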

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

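The exchanges of labels within replicate numbers, the count of calls left with the estimated depth and the test of exchanged labels in number 5 had their criteria set before their results were seen. The tests of the size of the differences under that depth correction, of genes with low values, of single replicate numbers, of the control axis and of the direction of number 5, and the splits without the block, were chosen after the results were seen.

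In 54 groups of 6 pools checked for a value far from the other 5 by Dixon's ratio, 6 passed the 95% limit, where chance gives 2.7. The control pool of replicate number 3 had 738 genes at a value of 5 or less, against 418 to 530 in the other control pools. The high pool of number 3 had 207 genes at 0, against 26 to 76 in the other high pools. ENSGACG00000010215 stood at 74 in low pool 4 (36 to 50 in the others), ENSGACG00000013120 at 5 in high pool 5 (13 to 15), ENSGACG00000013597 at 120 in high pool 2 (181 to 195) and ENSGACG00000018302 at 48 in high pool 1 (18 to 27).

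The first pattern is the 1300 genes called between high and low pools with the replicate block. Of 32 exchanges of the 2 labels within numbers, only the real one gave as many calls, and the highest other gave 123. That makes chance less likely but does not exclude it. A share of 1 of 32 is the smallest this test can give, and it was not adjusted over the tests of this kind. A single replicate number as the whole cause is argued against by the 505 or more calls left without any one of them. For sequencing depth, the criterion set beforehand was the share of calls left with the estimated reads as a covariate, with bounds of 10% and 66.7%, and the 400 calls left (30.8%) lay between them, so it did not decide; a second criterion, chosen only after that, was the median size of the called differences, which was 0.516 on the log2 scale (SE 0.15) with the covariate and 0.517 (SE 0.12) without, and so argues against depth as the source of the sizes, while the calls fell as the error grew. Of 9 covariates or pairs of covariates tried, the scores on control axes 1, 4 and 5 gave 1666, 947 and 1468 calls. The median sizes were 0.509, 0.524 and 0.533. The column total gave 707 calls with 0.448. The number of genes at a value of 5 or less left 36 calls with a median size of 0.318 (SE 0.14), and the score on the second control axis 0 calls with 0.300 (SE 0.18). That on the third axis left 55 calls with 0.399 (SE 0.16), and axes 1 and 2 together 4 calls with 0.290 (SE 0.17). Fewer measurable genes of low expression in some libraries thus remains a candidate explanation, as does a shift along the second or the third control axis. Without gene names neither axis could be tied to stage or tissue makeup, and no measure of the condition of the RNA was used here. Both scores and the number of genes at 5 or less separated high from low pools in 6 of 6 pairs. As covariates they raised the error, which by itself removes calls. Since these measures were computed from the same expression values, a response to cortisol would move them as well. The tests do not separate such a response from fewer measurable genes or from a shift along a control axis.

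The second pattern is the absence of calls between low and control pools with the block. As no exchange of labels can give fewer calls than the real 0, the 32 of 32 that gave as many say nothing of chance, and the highest, with the labels of number 5 alone exchanged, gave 412. In number 5 the low minus control difference correlated at r = -0.19 across genes with the mean of the other 5 numbers, while those others gave 0.10 to 0.42. Exchanged labels in number 5 may be a cause, and the test does not decide it: its high minus control difference had a mean r of 0.17 with the other numbers as labelled and 0.22 with its low library taken as the control, a difference of 0.0522. A response of those pools unlike the others is the biological alternative, which the single triplet cannot test.

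Without the block the real count was 0 in each of the 5 tests, so that 100 of 100 splits had to give as many and this says nothing of chance. The highest other split called 0 genes in low against control and in high against low, 122 in the F test, 3327 in high against control and 4904 in the trend. What the pools grouped in the splits with large counts had in common was not identified. The split with 3327 calls put 4 of 6 same-numbered pairs into 1 group each and that with 4904 put 9 of 18, while the other splits of high against control that kept at least 4 pairs together gave 0 calls, so that keeping numbers together was not enough for such counts. The 8 splits of high against control that parted every pair, as the real one does, gave 0 calls. With the block, 1 of 32 exchanges, the real one, gave as many calls as the 188 in high against control (highest other 1). Of 100 permutations, the real one included, 1 gave as many as the 853 in the F test (highest other 454). In the trend, 2 of 100 gave as many as the 4 (highest other 37). Explanations other than chance were not weighed for the 188 calls, which fell to 1 with the estimated reads as a covariate. They also fell to 1 with the score on the second control axis. The check of sizes under the depth covariate covered only the genes called between high and low pools.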

How the results depend on the processing

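The replicate block decided whether genes were called: it gave 188 calls for high against control, 1300 for high against low, 853 for the F test and 4 for the trend, all 0 without it, and 0 for low against control in both. The other 143 counts without the block, including each library left out, were 0. The settings that follow combine the block with 1 other choice and were added after the data were seen. For low against control, array weights gave 1067 and an adjusted p under 0.10 gave 15. For high against control, array weights gave 602, the looser threshold 506, no variance trend 19, and as covariates the estimated reads 1, the column total 440, the number of genes at 5 or less 59, control axes 2 and 3 1 and 35, and axes 1 and 2 together 11. For high against low these gave 2491, 2150, 857, 400, 707, 36, 0, 55 and 4. For the F test, array weights gave 2594, the looser threshold 1643 and no variance trend 391. For the trend these gave 67, 34 and 0, and no filter, the stricter filter, quantile normalization and the robust fit gave 0 each. Leaving out 1 library or 1 replicate number gave 0 to 372 calls for low against control, 18 to 265 for high against control, 505 to 1579 for high against low, 256 to 1301 for the F test and 0 to 11 for the trend; replicate number 3 gave the lowest count in high against control, high against low and the F test. The correlation of the low and high effects turned to -0.44 when only the controls were split into sets of 3, which then hold different replicate numbers and so carry the differences between numbers with opposite signs. The 12 genes chosen by smallest p kept their direction in all 294 values under alternatives, and 8 passed the threshold with the block. The kept direction is no independent support. These genes were chosen in the same data, the alternatives reuse most or all of the libraries, and the block leaves the fold changes as they were. In the simulation of high against control, changes of 0.5 on the log2 scale were found in 45.5% of cases with the block; smaller changes were not simulated. The edgeR test planned for deposited raw counts was not run, as the deposited values had been scaled. The planned gene list and ABC transporter tests were not run for want of gene names.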

Other observations

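Agreement between replicate numbers differed by comparison. The high minus low difference of each replicate number correlated with the mean of the other 5 at r = 0.22 (number 2) to 0.54 (number 6), and the high minus control difference at 0.14 (number 2) to 0.37 (number 3). Replicate number 2 had the lowest value in both. The low minus control difference was most alike between the other numbers and number 6 (0.42) and number 1 (0.36), which also lay together on the first principal component. These correlations are across genes, which are not independent replicates, and each is a single value with no test.

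Deposited totals and depth moved apart. The totals of the normalised values differed by replicate number, from 8.36 M in low pool 1 to 15.2 M in high pool 5, while the estimated reads ran from 9.65 to 12.4 M. The 100 most abundant genes took 21.5% to 40.3% of the total across the 18 pools.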
